A study of Mus musculus with 5 samples.

How the data were processed

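Intestinal adenomas of ApcMin/+ mice on a C57BL/6 background were dissociated with enzymes and run on a 10x Chromium single-cell 3' platform, per the labels' protocols. Libraries were grouped by the treatment label into AAV-RSPO1-Fc (3) and AAV-Ctrl (2). The authors deposited UMI counts per gene and barcode for every barcode, with no cell filter and no normalization. Reads were processed with Cell Ranger 2.1.1 against mm10, per the labels, and Seurat 3.1.1 is named in the submitters' processing notes. The deposited counts of the D1-2 set name Cell Ranger 3.1.0, per the file headers, and those of the D4 set name no software. The D4 libraries list 27998 genes and 737280 barcodes and the D1-2 set lists 31053 genes and 6794880 barcodes, which are not the lists of 1 chemistry, although the labels name 1 kit for all libraries. Set, chemistry and gene list were therefore confounded, and treated and control libraries were compared only within a set. The 27514 genes found in both lists were used, which held at least 98.9% of the UMIs of each library. Genes are named by the symbols that the files pair with Ensembl identifiers. No authors' cell annotation was used here, and the reference genome was not needed.

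Cells were called per library as barcodes with at least 10% of the UMI count at the 99th percentile of the top 5000 barcodes, the number of cells the protocol aimed for, and at least 500 UMIs. This set the UMI minimum at 5045, 5094, 10280 (10279.8), 8741 and 9519.5 in AAV-Ctrl D4, AAV-RSPO1-Fc D4, AAV-Ctrl D1-2, AAV-RSPO1-Fc D1 and AAV-RSPO1-Fc D2, so that small cells such as lymphocytes were mostly left out, and 0 T cell-like cells were kept. Cells needed at least 300 genes and at most 20% mitochondrially encoded UMIs. Scrublet, as implemented in scanpy, marked 0.10% to 0.38% of cells by its automatic threshold, which is too few to have worked. By the rule set beforehand, the highest-scoring cells were removed instead, at a rate of 0.8% per 1000 cells (1.56% to 2.96% of cells). The median UMI count per kept cell was 17176 (17175.5), 15701, 23463, 22824 and 23039 (23038.5), in the same order.

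Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen within set, then centred and scaled within set, and 30 principal components, 15 nearest neighbours and Leiden resolution 1.0 gave 33 clusters. Mitochondrial, ribosomal, sex-linked and stress genes and the Wnt target, normal stem cell, adenoma, TGF-beta and BMP lists were kept out of the clustering, since their levels are compared. A cluster took the name of the class with the highest mean log2 fold of its fixed markers over the median of the clusters. It needed at least 3 markers 2-fold higher and found in 10% of its cells, a mean log2 fold of at least 1.0, and no more markers of another class than of its own among its 10 leading genes. The rule set beforehand asked for the class with most markers among the leading genes and at least 3 detected markers. The fold and share minimums, and a list of gastric genes of which 3 among the leading genes left a cluster unnamed, were added after the clusters were seen. Classes are called "like" because they rest on these markers. Epithelial-like clusters are those of an epithelial name, and unnamed ones with at least 8 of 12 general epithelial markers in 25% of their cells.

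Counts were summed per library over epithelial-like cells, and over each named class with at least 20 cells in every library. Treated and control sums were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, TMM scaling, filterByExpr, set as a covariate, 2 residual degrees of freedom, Benjamini-Hochberg adjustment, threshold 0.05). The treated libraries carry different D labels, so the spread includes any difference between those labels. An interaction of set and treatment tested whether the difference differed between sets (1 residual degree of freedom). Of 22 gene lists fixed before the data were examined, 20 were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists), and again with an estimated correlation and with fry. They were Wnt target, normal intestinal stem cell, adenoma, TGF-beta response, BMP response, proliferation, enterocyte, goblet, Paneth, enteroendocrine, tuft, fetal and regenerative, interferon-stimulated, MHC class II, antimicrobial and alarm, p53 target, ribosome biogenesis, dissociation stress, hypoxia and mitochondrially encoded genes. The Wnt target, normal stem cell and adenoma lists share members. The markers of the adenoma-like class were all members of the Wnt target list, and Prox1, Notum, Nkd1, Wif1 and Dkk2 also of the adenoma list. Those of the cycling progenitor-like class were all members of the proliferation list. Tests of these lists within or without these classes are therefore not independent of the naming. Single comparisons of 1 treated and 1 control library used log2 ratios of TMM-scaled CPM with a prior count of 2.0, with no test. Medians of lists were placed among 10000 random lists matched on mean expression in 20 bins. Shares of epithelial-like cells were compared by an exact two-sided permutation test with treatment exchanged within set (6 splits), added after the data were seen. CPM of named genes carry 95% exact Poisson intervals and shares 95% exact binomial (Clopper-Pearson) intervals.

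Genes were named by a rule fixed before the data were examined. It took the list members with the lowest p, 2 to 4 per list, and Rspo1, Lgr4, Lgr5, Lgr6, Znrf3, Rnf43, Apc and Ctnnb1. It also took up to 10 genes per direction that passed the epithelial test, up to 8 per direction with the same direction in all 3 single comparisons at a CPM of at least 50 ranked by their smallest ratio, and up to 5 per direction that passed in a class. Gene models, immunoglobulin and T cell receptor segments, ribosomal protein and sex-linked genes were counted and not named. The text says where a gene was chosen after its values were seen.

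The test was run on simulated counts with the means and library sizes of the real epithelial sums and 200 genes changed. Every simulated gene had the same spread and no difference between sets, and only better expressed genes were changed. At the spread of the real test (biological coefficient of variation 0.282) it recovered 10 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, with 0 of the wrong sign and 4 false calls among 15497 genes. At a coefficient of 0.224 it recovered 38 and 100, and at 0.1 it recovered 100 and 100. Alternatives were DESeq2 1.42.0, library totals without TMM, no filter on low counts, no set covariate, each library left out, a mitochondrial limit of 10%, doublets kept, a minimum of 1500 UMIs, Leiden resolutions of 0.5 and 2.0, list genes left in the clustering, thinned counts, prior counts of 0.5 and 10, and a CPM minimum of 200. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.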

Results

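Single-cell RNA sequencing counts were analysed from dissociated intestinal adenomas of ApcMin/+ mice, which carry a truncating mutation in Apc, a negative regulator of Wnt signalling, and form such adenomas spontaneously. The mice had received an adeno-associated virus (AAV), either empty (AAV-Ctrl, 2 libraries) or encoding RSPO1-Fc (AAV-RSPO1-Fc, 3 libraries). RSPO1 is a secreted protein that binds the receptors Lgr4, Lgr5 and Lgr6 and holds back Znrf3 and Rnf43, which remove Wnt receptors from the cell surface. The question was how epithelial cells of the adenomas differed after AAV-RSPO1-Fc. AAV-Ctrl replicate 1 and AAV-RSPO1-Fc replicate 1 were labelled D4, and AAV-Ctrl replicate 2 was labelled D1-2. AAV-RSPO1-Fc replicates 2 and 3 were labelled D1 and D2, and the labels do not expand D. Each treated library was compared within its set, so that D1 and D2 shared 1 control library. Total UMI counts were 48049930 in AAV-Ctrl D4, 56750900 in AAV-RSPO1-Fc D4, 138386744 in AAV-Ctrl D1-2, 130782670 in AAV-RSPO1-Fc D1 and 124170262 in AAV-RSPO1-Fc D2. After filtering, 1896, 2346, 2959, 3600 and 3036 cells were kept in that order. The labels do not say whether the libraries came from separate animals. Sex-linked transcripts, given below, were of both sexes in AAV-Ctrl D1-2 and D1, and almost only Xist in D2. The libraries of that set therefore did not hold the same mix of animals. P-values measure the spread between these samples, which may be technical in part. Intervals on shares and CPM are 95% exact intervals and cover counting error only.

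Rspo1 transcripts were nearly absent from epithelial-like cells of the control libraries and present in 2 of the 3 treated ones. AAV-Ctrl D4 held 1 UMI and AAV-Ctrl D1-2 held 2, whereas AAV-RSPO1-Fc D1 held 160 (1.62 CPM, 1.38 to 1.89) and AAV-RSPO1-Fc D2 held 185 (2.05 CPM, 1.77 to 2.37). AAV-RSPO1-Fc D4 held 3 UMIs (0.069 CPM, 0.014 to 0.202), which was not distinguishable from its control at this depth. The counts do not show whether the vector was expressed in the mice of that library. The receptor gene Lgr5, a stem cell marker, was at 19.96 CPM in AAV-Ctrl D4 and 9.96 in AAV-RSPO1-Fc D4, and at 47.9 in AAV-Ctrl D1-2 against 57.6 in D1 and 51.1 in D2. Lgr4 went from 124 to 71.9 CPM in D4, and stood at 82.7 in AAV-Ctrl D1-2, 114 in D1 and 86.7 in D2. Lgr6 had no UMI in AAV-RSPO1-Fc D4 (up to 0.085 CPM) and 0.559 CPM in its control, and lay between 2.32 and 2.86 CPM in the other set. Znrf3 stood at 36.0 and 8.33 CPM in the D4 pair, and at 27.7, 36.3 and 28.3 in AAV-Ctrl D1-2, D1 and D2. Rnf43 was at 27.8 and 24.7 CPM in the D4 pair, and at 73.2, 86.9 and 82.3 in the other set. Apc was at 35.5 and 33.9 CPM in D4, and at 57.8, 60.7 and 61.7 in the other set. Ctnnb1, which encodes beta-catenin, was at 413 and 301 CPM in D4, and at 436, 389.6 and 399 in the other set. None of these 8 genes passed the pooled test of 2 against 3 libraries (adjusted p of at least 0.686 by edgeR's quasi-likelihood test). These values cover all epithelial-like cells, whose classes differed between libraries. Without the adenoma-like and unnamed clusters, an alternative added after the data were seen, the pooled log2 fold changes of Lgr5 (0.71) and Znrf3 (0.29) were above 0 rather than below. The adenoma-like clusters were named on members of the Wnt target list, which holds Lgr5 and Znrf3, so this change is not independent of the naming.

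Adenoma-like cells, named from Wnt target and Wnt inhibitor genes, made up a smaller part of the epithelium in AAV-RSPO1-Fc D4 than in its control, and a larger part in D1 and D2. Their share of epithelial-like cells was 22.0% (20.1 to 24.0, 405 of 1841 cells) in AAV-Ctrl D4 and 4.53% (3.71 to 5.48, 102 of 2250) in AAV-RSPO1-Fc D4. It was 24.4% (22.8 to 26.0, 689 of 2828) in AAV-Ctrl D1-2, 35.8% (34.2 to 37.4, 1215 of 3394) in D1 and 33.7% (32.0 to 35.5, 1004 of 2977) in D2. Stem-like cells were 5.65% (4.64 to 6.80) of epithelial-like cells in AAV-Ctrl D4 and 19.5% (17.8 to 21.2) in AAV-RSPO1-Fc D4, in 1 cluster of 554 cells of which the latter library gave 438. In the other set stem-like cells were at most 0.177%. The cluster was named on 4 markers (Smoc2, Slc12a2, Gkn3 and Cdca7) at a mean log2 fold of 1.01, near the minimum of 1.0. Lgr5, Olfm4 and Ascl2 were not among them, so its share does not give the share of cells with these stem cell genes. Cycling progenitor-like cells were 9.29% and 30.0% in the D4 pair, 3.25% in AAV-Ctrl D1-2, 4.83% in D1 and 12.1% in D2. Other clusters held most of this class in the D4 set (7 and 18) than in the D1-2 set (9). These shares leave out an unnamed cluster whose best class was cycling progenitor. It held 45 and 1 cells of the D4 pair, and 242, 359 and 284 of AAV-Ctrl D1-2, D1 and D2. In AAV-Ctrl D1-2 and D1 it was larger than the named class (92 and 164 cells). Enterocyte-like cells, the absorptive cells, were 35.9% and 36.6% in the D4 pair, and 31.6%, 13.2% and 18.1% in AAV-Ctrl D1-2, D1 and D2. Goblet-like cells, which secrete mucus, were 2.77% and 6.49% in the D4 pair, and 4.35%, 2.33% and 3.53% in the other set.

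Epithelial clusters left unnamed were 23.3% of epithelial-like cells in AAV-Ctrl D4, 0.400% in AAV-RSPO1-Fc D4, 35.4% in AAV-Ctrl D1-2, 42.7% in D1 and 31.9% in D2. With those unnamed clusters whose best class was adenoma added, a grouping made after the data were seen, the adenoma-like share was 37.8% and 4.84% in the D4 pair, and 42.4%, 59.9% and 49.0% in the other set. An exact two-sided permutation test of the 9 epithelial shares, with treatment exchanged within set and added after the data were seen, has 6 splits and a smallest p of 0.167, so that no share can pass (lowest p = 0.333 by this permutation, for cycling progenitor-like and enterocyte-like cells). The libraries also differed in the sex of their cells. In AAV-RSPO1-Fc D2, 99.2% of cells had Xist and no Y-linked UMI, against 66.0% in D1 and 48.3% in AAV-Ctrl D1-2. Both D4 libraries held Y-linked UMIs without Xist in most cells (69.6% and 77.2%). Among cells with Xist and no Y-linked UMI the adenoma-like share was 25.2% in AAV-Ctrl D1-2, 37.0% in D1 and 33.9% in D2. Among cells with Y-linked UMIs and no Xist it was 24.2% (21.9 to 26.6) and 4.51% (3.59 to 5.59) in the D4 pair, and 25.0% (22.2 to 28.1) in AAV-Ctrl D1-2 and 34.6% (31.1 to 38.2) in D1.

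**Figure D1:**
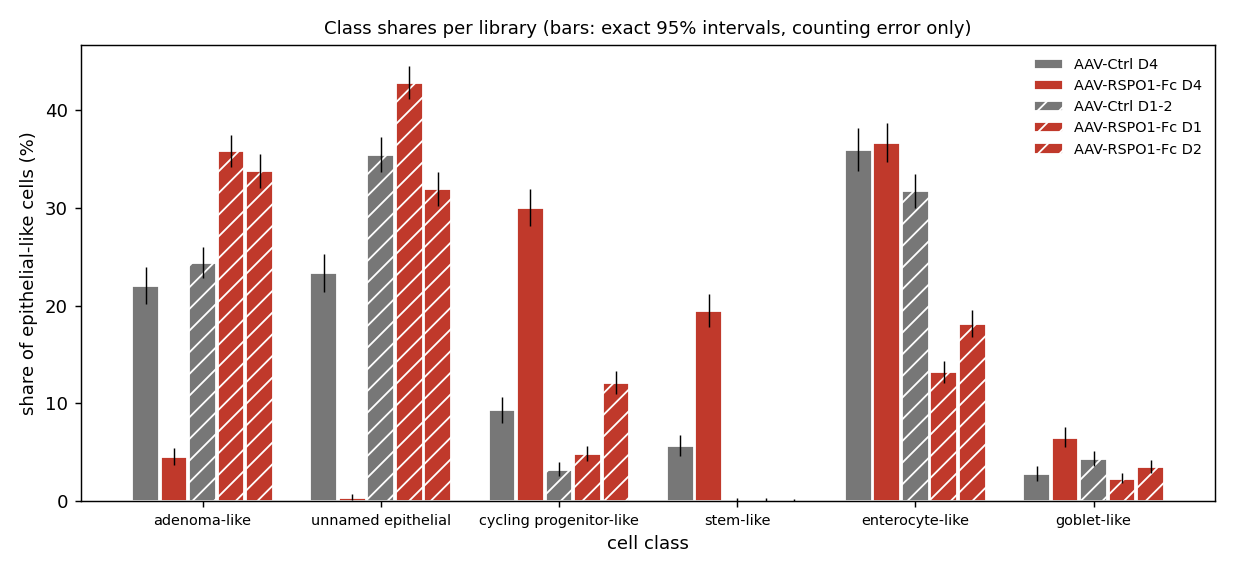
Share of epithelial-like cells (y axis, percent) for the 5 libraries, with 95% exact binomial intervals. Groups are adenoma-like, unnamed epithelial, cycling progenitor-like, stem-like, enterocyte-like and goblet-like cells. Adenoma-like cells were 4.53% in AAV-RSPO1-Fc D4 against 22.0% in its control, and 35.8% and 33.7% in D1 and D2 against 24.4%.

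Wnt target and adenoma genes did not move alike in treated epithelium, and several of them were far lower in D4 while others were higher. The 4 members of the Wnt target list with the lowest p were Myc (log2 0.64, 0.38 and 0.50 in D4, D1 and D2), Ascl2 (0.32, 0.49 and 0.42), Ephb2 (0.86, 0.05 and 0.36) and Dkk2 (−4.89, −0.93 and −0.41), each with adjusted p = 0.686 in the pooled test. Those of the adenoma list were Cldn2 (0.90, 0.32 and 0.64), Sox4 (0.74, 0.35 and 0.25), Gpx2 (0.52, 0.30 and 0.79) and Wnt10a (−4.33, −0.95 and −0.53), with the same adjusted p. The other genes named here were chosen after their values were seen. Nkd1, which encodes a Wnt pathway inhibitor, was at 179 CPM (174 to 183) in epithelial-like cells of AAV-Ctrl D4 and at 14.2 CPM (13.1 to 15.4) in AAV-RSPO1-Fc D4. It was at 256 CPM in AAV-Ctrl D1-2, 307 in D1 and 277 in D2. Notum, a secreted Wnt deacylase, was at 103 and 6.73 CPM in the D4 pair, and at 139, 189.6 and 166 in AAV-Ctrl D1-2, D1 and D2. Prox1, a transcription factor of intestinal adenomas, was at 102 and 8.21 CPM in D4, and at 185, 243 and 186 in the other set. Axin2, a general Wnt target, moved less, at 36.4 and 30.1 CPM in D4 and at 99.5, 117 and 105 in the other set. The median log2 ratio of the 22 Wnt target genes was −1.09 in D4, 0.24 in D1 and 0.11 in D2. Among 10000 random lists of matched expression these medians lay at percentiles 0, 99.98 and 88.5. For the 14 adenoma genes the medians were −3.63, 0.25 and 0.06, at percentiles 0, 99.8 and 61.4. Percentiles describe these libraries and are not tests. With 1 library per group the single comparisons had no replicate check.

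**Figure D2:**
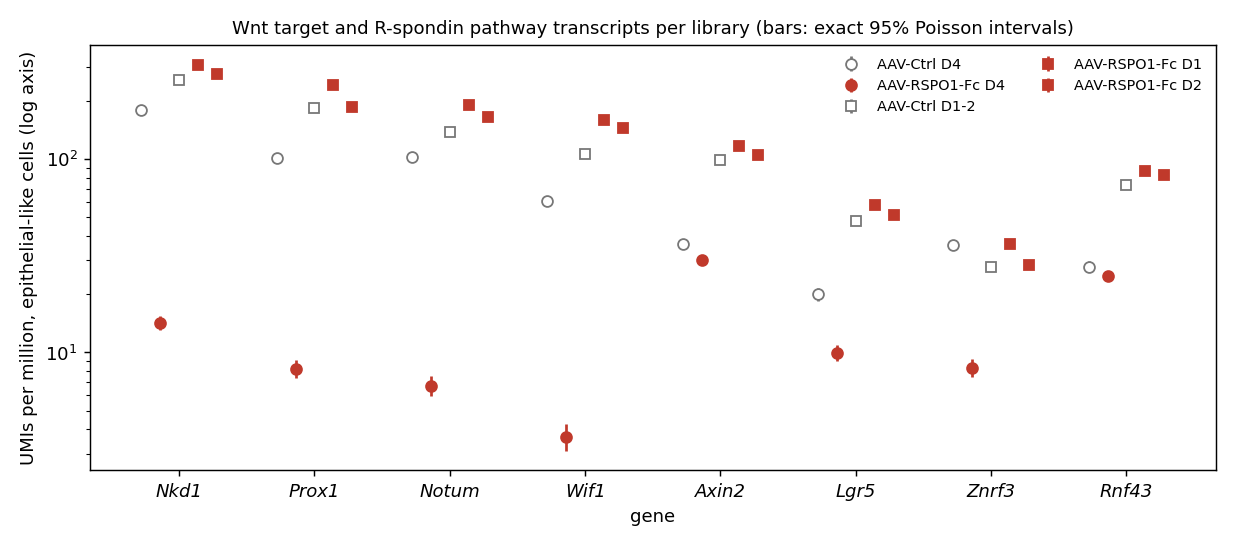
CPM (y axis, log scale) of R-spondin receptor and Wnt target genes in epithelial-like cells of each library, with 95% exact Poisson intervals. Nkd1 was at 14.2 CPM in AAV-RSPO1-Fc D4 against 179 in its control, and at 307 and 277 in D1 and D2 against 256.

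Over all 5 libraries, with set as a covariate, treated epithelium showed higher ribosome biogenesis, proliferation and normal stem cell genes and lower enterocyte, fetal and interferon-stimulated genes as groups. Of the 16 ribosome biogenesis genes all 16 had higher values, among them Dkc1 (log2 0.49, SE 0.111) and Ncl, nucleolin (0.49, SE 0.121), at medians of 0.31, 0.38 and 0.42 in D4, D1 and D2. By camera this list rose (adjusted p = 4.83e-09; adjusted p = 0.291 with an estimated correlation), with 0 members passing when adjusted over the list alone. With the preset correlation it rose in cycling progenitor-like (adjusted p = 0.000432), enterocyte-like (0.00875) and goblet-like cells (0.0036). In adenoma-like cells it did not pass (camera adjusted p = 0.074). Its D4 medians in adenoma-, cycling progenitor-, enterocyte- and goblet-like cells were 0.11, −0.01, 0.15 and −0.03. Of 30 proliferation genes 29 had higher values, among them Ccnb2 (0.57, SE 0.143) and Cenpa (0.39, SE 0.126). That list rose (adjusted p = 2.06e-09; adjusted p = 0.613 with an estimated correlation), with 0 members adjusted over the list alone. The cycling progenitor-like share was higher too (30.0% against 9.29% in D4, and 4.83% and 12.1% against 3.25% in D1 and D2). It leaves out an unnamed cluster of that best class, with 45 and 1 cells in the D4 pair and 242, 359 and 284 in the other set. In D1 the difference from control varied with the sex-linked transcripts of the cells, in 1 library per group with the number of animals unknown. Cells with both Xist and Y-linked UMIs were left out of these shares. Among cells with Xist and no Y-linked UMI the share was 4.39% (3.6 to 5.3) against 5.03% (3.9 to 6.3) in its control, with overlapping intervals. Among cells with Y-linked UMIs and no Xist it was 5.18% (3.7 to 7.1) against 0.93% (0.4 to 1.8). Within classes the proliferation list did not pass by camera (adjusted p = 0.279 in adenoma-like, 0.927 in cycling progenitor-like, 0.06 in enterocyte-like and 0.613 in goblet-like cells). The cycling progenitor-like class was named on members of this list, so its result there is not independent of the naming. Of 16 normal stem cell genes 10 had higher values, among them Slc12a2, an ion cotransporter of crypt cells (0.80, SE 0.158), and Cdca7 (0.90, SE 0.216). The list rose (adjusted p = 0.00723; adjusted p = 0.357 with an estimated correlation), with 0 members adjusted over the list alone, and its median in D4 was −0.08. Its call was lost without AAV-Ctrl replicate 2 (adjusted p = 0.358), a fit in which the D4 pair alone sets treated against control.

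Of 18 enterocyte genes 16 had lower values, among them Apob, of lipoprotein assembly (−1.18, SE 0.112), and the keratin Krt20 (−1.13, SE 0.134), at list medians of −0.34, −0.63 and −0.84 in D4, D1 and D2. The list fell (adjusted p = 9.51e-16; adjusted p = 0.27 with an estimated correlation), with 6 members adjusted over the list alone. The enterocyte-like share was lower in D1 and D2 (13.2% and 18.1% against 31.6%), so that there the list moved with the share of these cells, and was not lower in D4 (36.6% against 35.9%). All 16 measured fetal and regenerative genes had lower values, among them Il1rn (−0.83, SE 0.128) and Krt7 (−0.85, SE 0.179), at list medians of −1.30, −0.44 and −0.14. That of D2 lay within the central 95% of random lists (−0.15 to 0.17). They fell as a list (adjusted p = 1.28e-06; adjusted p = 0.378 with an estimated correlation), with 2 members adjusted over the list alone. By camera with the preset correlation they fell in cycling progenitor-like (adjusted p = 0.0278), enterocyte-like (1.15e-09) and goblet-like cells (1.04e-07). In adenoma-like cells they did not pass (adjusted p = 0.279), with a median of 0.30 in D4. All 20 interferon-stimulated genes had lower values, with Ifit1 at −1.93 (SE 0.690) and list medians of −0.62, −1.81 and −0.28. This list fell (adjusted p = 4.19e-07; adjusted p = 0.572 with an estimated correlation), with 0 members adjusted over the list alone. TGF-beta response genes had lower values in 18 of 20, among them the cell cycle inhibitors Cdkn1a (−0.45, SE 0.108) and Cdkn2b (−0.83, SE 0.213). They fell as a list (adjusted p = 0.000843; adjusted p = 0.32 with an estimated correlation; 0 members adjusted over the list alone). Within classes the TGF-beta response list fell in goblet-like cells (camera adjusted p = 0.0279, or 0.599 with an estimated correlation). It did not pass in adenoma-like (camera adjusted p = 0.074), cycling progenitor-like (0.25) or enterocyte-like cells (0.06). Its D4 medians were 0.07 in adenoma-like and 0.19 in cycling progenitor-like cells. Without AAV-Ctrl replicate 2 the calls of the interferon-stimulated (adjusted p = 0.192) and TGF-beta response lists (adjusted p = 0.0657) were lost.

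Hypoxia genes were lower in 12 of 14, with Egln3 at −0.78 (SE 0.147) and the glucose transporter Slc2a1 at −0.85 (SE 0.219), and fell as a list (adjusted p = 0.00117; adjusted p = 0.32 with an estimated correlation; 0 members adjusted over the list alone). Within classes they fell in enterocyte-like cells (camera adjusted p = 0.0136, or 0.65 with an estimated correlation) and did not pass in goblet-like cells (0.212). In adenoma-like and cycling progenitor-like cells 8 and 10 of 14 had higher values, and the list did not pass (camera adjusted p = 0.483 and 0.15). The 13 mitochondrially encoded genes, often read as a sign of cell quality, all had lower values and fell as a list (adjusted p = 0.00312; adjusted p = 0.65 with an estimated correlation; 0 members adjusted over the list alone). Their call was lost with at most 10% mitochondrial UMIs per cell (adjusted p = 0.0587), without AAV-RSPO1-Fc replicate 2 (adjusted p = 0.0677) and without AAV-Ctrl replicate 2, where camera gave the opposite direction (median −0.05, adjusted p = 0.873). Median mitochondrial shares per cell were 6.35% and 6.62% in the D4 pair, and 7.28%, 5.68% and 6.06% in AAV-Ctrl D1-2, D1 and D2.

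The remaining calls rested on the D4 set. Adenoma genes fell as a list in the pooled test by camera (adjusted p = 0.0362, or 0.65 with an estimated correlation), with 11 of 14 lower and a median of −1.55. Adjusted over the list alone, 0 members passed. The call was lost without the set covariate (camera adjusted p = 0.409). It was also lost without the adenoma-like and unnamed epithelial clusters, an alternative added after the data were seen (camera adjusted p = 0.0768). The adenoma-like clusters were named on members of this list, so that loss cannot show whether the genes changed within cells. Without AAV-Ctrl replicate 1 the median was 0.13 (adjusted p = 0.155), and without AAV-RSPO1-Fc replicate 1 also 0.13 (adjusted p = 0.162). MHC class II genes, which present antigen, rose as a list (adjusted p = 0.00465; adjusted p = 0.64 with an estimated correlation; 0 members adjusted over the list alone). Their medians were 2.88, −0.54 and −0.18 in D4, D1 and D2, and −0.33 in the pooled fit without AAV-Ctrl replicate 1, where the list fell (adjusted p = 0.0395), or without AAV-RSPO1-Fc replicate 1 (adjusted p = 0.0592). Macrophage and monocyte-like cells, which express these genes, were 0.264% and 1.62% of kept cells in the D4 pair, and 0.406%, 1.75% and 0.165% in the other set. Within adenoma-, cycling progenitor-, enterocyte- and goblet-like cells the list medians in D4 were 2.52, 2.36, 3.02 and 2.80, and in D1 and D2 they were of mixed sign. The source of these transcripts was not tested.

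The other 9 lists tested did not pass, and the 2 lists of sex-linked and R-spondin genes were not tested as lists. Wnt target genes had lower values in 15 of 22 (adjusted p = 0.17), BMP response genes in 10 of 10 (0.0663), and p53 target genes in 11 of 14 (0.122). Goblet genes had lower values in 7 of 13 (adjusted p = 0.158), Paneth genes in 8 of 12 (0.0664), tuft genes in 7 of 10 (0.218) and enteroendocrine genes in 11 of 14 (0.564). Dissociation stress genes had lower values in 16 of 18 (adjusted p = 0.0663). Antimicrobial and alarm genes had higher values in 9 of 14 and a median of 0.46, whereas camera gave the opposite direction (adjusted p = 0.281). Counts adjusted over the list alone were 2 for antimicrobial, 1 for goblet (Zg16) and 1 for Paneth genes (Defa21), and 0 for the others.

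Gene by gene, 0 of 15765 genes passed in either direction by edgeR's quasi-likelihood test (lowest adjusted p 0.485), while 1121 had an unadjusted p under 0.05. DESeq2 called 35 higher and 145 lower. Without AAV-Ctrl replicate 2, when the D4 pair alone sets treated against control, the quasi-likelihood test called 70 higher and 719 lower. These calls compare 1 library with 1, at a spread taken from D1 against D2 alone. At the common spread of these libraries the test recovered 10% of simulated 2-fold and 92% of 4-fold changes. The simulation gave every gene the same spread and no difference between sets, and changed only better expressed genes. These rates therefore do not carry over to all real genes, and Mcpt1 at log2 −3.645 did not pass the quasi-likelihood test (adjusted p = 0.485). No list passed with an estimated correlation.

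**Figure D3:**
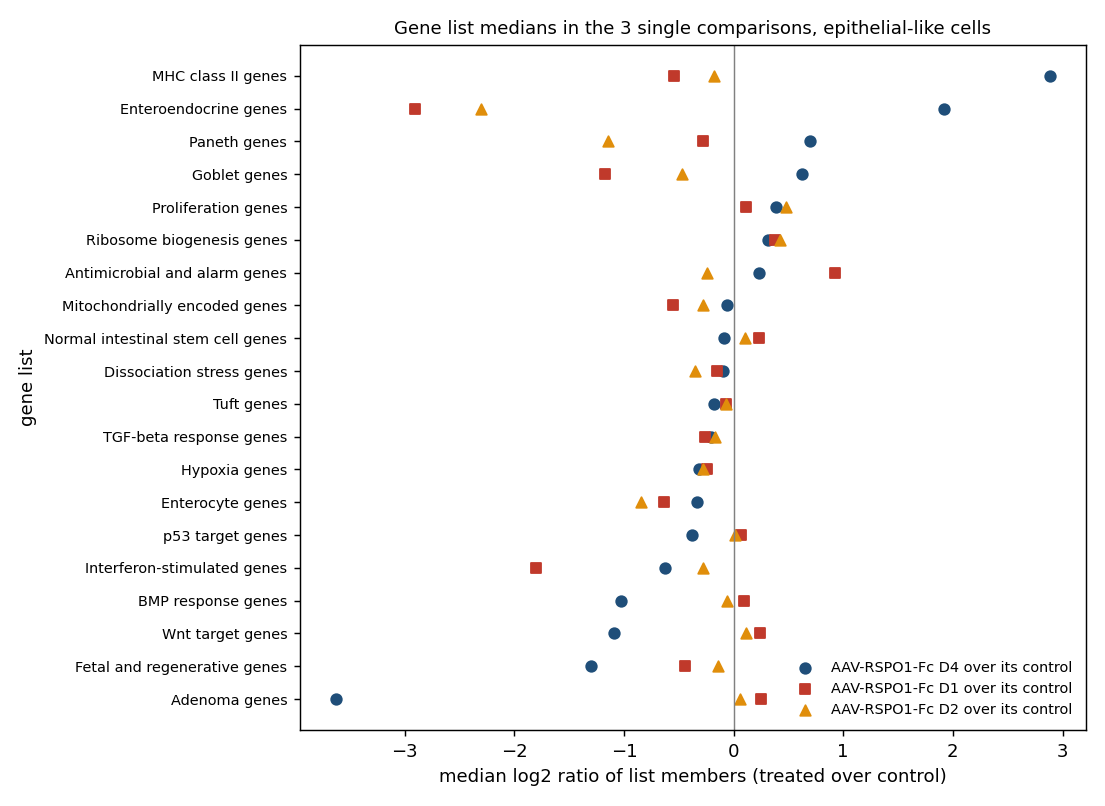
Median log2 ratio of treated over control (x axis) for each fixed gene list in epithelial-like cells, 1 point per single comparison. Ribosome biogenesis genes lay above 0 in D4, D1 and D2 (0.31, 0.38 and 0.42), whereas adenoma genes were at −3.63 in D4 and at 0.25 and 0.06 in D1 and D2.

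Some genes were lower in each of the 3 single comparisons. With a CPM of at least 50 in the higher library, 15 genes were at least 2-fold lower in D4, D1 and D2. D1 and D2 share a control, and 47 genes were lower in both. Of the 2533 genes at the CPM minimum in all 3 comparisons, 36 were lower in both and 135 in D4, and independent lists of these sizes would share 1.92. No gene was 2-fold higher in both D1 and D2, so that 0 were higher in all 3. Those with the largest smallest ratio included Mcpt1 and Mcpt2, proteases of mucosal mast cells (log2 −4.52, −3.47 and −2.62, and −3.70, −2.55 and −2.35, in D4, D1 and D2). Zg16, a goblet cell lectin, followed (−1.58, −1.70 and −1.77), with Duoxa2, a maturation factor of the oxidase Duox2 (−1.57, −2.18 and −1.61), and Pmp22 (−2.31, −1.54 and −1.40). Defa21, a Paneth cell defensin of a family of near-identical genes whose reads can be shared, was at −1.38, −1.99 and −2.35. Sprr1a was at −1.74, −1.46 and −1.32, and Cd55, which limits complement, at −2.005, −2.14 and −1.19. Higher in all 3 were Slc12a2 (1.10, 0.55 and 0.61), Cdca3 (0.52, 0.52 and 0.54), Rangrf (0.73, 0.50 and 0.54), Ncl (0.43, 0.60 and 0.45), Ppp1r14b (0.77, 0.44 and 0.42), Vars (0.66, 0.41 and 0.41), Dnajc2 (0.44, 0.40 and 0.48) and Hook1 (0.72, 0.68 and 0.40). None of these 16 genes passed the pooled test (lowest adjusted p 0.485). Of 162 genes at least 2-fold lower in D4, 26 were also among the 92 lower in D1 and 16 among the 63 lower in D2. Of the 2566 genes that reached the CPM minimum in both D4 and D1, 135 and 76 were lower, and independent lists of these sizes would share 4. Of the 2587 that did so in D4 and D2, 137 and 50 were lower, and independent lists would share 2.65. Of 46 higher in D4, 1 was shared with the 9 in D1 and 1 with the 2 in D2. Independent lists would share 0.07 among the 2566 genes (22 and 8 higher) and 0.02 among the 2587 (22 and 2 higher). Mast cell-like cells were 1.48% of kept cells in AAV-Ctrl D4 (28 cells) and 0.256% in AAV-RSPO1-Fc D4 (6 cells), and 0.169%, 0.139% and 0.066% in AAV-Ctrl D1-2, D1 and D2 (5, 5 and 2 cells). With a minimum of 1500 UMIs, which keeps more immune cells, they were 3.18% and 0.143% in the D4 pair, and 1.53%, 0.257% and 0.411% in the other set.

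By an interaction test whose spread came from D1 against D2 alone, the treatment difference differed between the D1-2 set and the D4 pair, among others in adenoma, Wnt target, MHC class II and enteroendocrine genes. Over 16384 genes it called 346 whose difference was higher in the D1-2 set and 45 whose difference was lower (edgeR's quasi-likelihood test, 2684 with an unadjusted p under 0.05). The named genes here were chosen after their values were seen. Wif1, a Wnt inhibitor, had log2 ratios of −4.04, 0.51 and 0.41 in D4, D1 and D2 (adjusted p = 0.00693), Notum −3.92, 0.37 and 0.22 (adjusted p = 0.00693) and Ifitm1 −4.10, −0.08 and −0.12 (adjusted p = 0.00693). In the other direction Cd74, the MHC class II invariant chain, had 3.45, −0.74 and −0.29 (adjusted p = 0.0121), H2-Aa 3.51, −0.44 and −0.17 (adjusted p = 0.0139), and the hormone gene Sct 2.01, −1.90 and −1.44 (adjusted p = 0.0137). Of 14 adenoma genes 9 passed and 11 did so adjusted over the list alone (camera adjusted p = 6.85e-26; adjusted p = 0.678 with an estimated correlation). Of 22 Wnt target genes 9 passed and 13 adjusted over the list alone (adjusted p = 1.12e-19; adjusted p = 0.678 with an estimated correlation). For MHC class II genes these counts were 4 and 7 of 7 (adjusted p = 3.52e-17; adjusted p = 0.678 with an estimated correlation), and for enteroendocrine genes 3 and 9 of 14 (adjusted p = 4.92e-16; adjusted p = 0.678 with an estimated correlation). The median log2 difference, D1-2 set minus D4, was 3.77 for adenoma, 1.17 for Wnt target, −3.39 for MHC class II and −4.11 for enteroendocrine genes, and −1.57 for goblet and −1.41 for Paneth genes, which passed too (adjusted p = 4.31e-08 and 7.79e-08; 0.678 for both with an estimated correlation). Fetal and regenerative genes passed as well, at 1.08 (adjusted p = 7.08e-07; adjusted p = 0.678 with an estimated correlation; 5 of 16 members passing), and BMP response, p53 target and mitochondrially encoded genes at 1.13, 0.47 and −0.33 (adjusted p = 0.00117, 0.00518 and 0.0106; 0.678, 0.678 and 0.917 with an estimated correlation). Enteroendocrine-like cells were 9, 34, 9, 4 and 2 in AAV-Ctrl D4, AAV-RSPO1-Fc D4, AAV-Ctrl D1-2, D1 and D2. With 1 residual degree of freedom and 1 library per group in D4, the test cannot tell a difference between sets from 1 unusual D4 library.

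Within goblet-like cells, mast cell and enterocyte transcripts were among those that fell in treated libraries. Mcpt2 (log2 −4.43, SE 0.275, adjusted p = 0.000336) and Mcpt1 (−4.23, SE 0.354, adjusted p = 0.00258) fell in 3 of 3 comparisons, from 54 and 510 Mcpt2 UMIs in the controls to 3, 16 and 26 in AAV-RSPO1-Fc D4, D1 and D2. In AAV-Ctrl D1-2, 72.2% of the UMIs of both genes in goblet-like cells lay in 4 of 123 cells. Without cells that held at least 10 of these UMIs the log2 ratios of their CPM were −5.96, −2.70 and −2.01 in D4, D1 and D2. The apolipoprotein gene Apoa1, of enterocytes, fell by 2.08 on the log2 scale (SE 0.205, adjusted p = 0.00556). So did Slc34a2, a phosphate transporter (−3.61, SE 0.335, adjusted p = 0.00429), and Serpina1b, a protease inhibitor (−2.45, SE 0.254, adjusted p = 0.00697). In the D4 pair Slc34a2 had a ratio of −2.01 at 1.67 and 0 CPM, and Serpina1b one of −0.55 at 1.67 and 0.97 CPM. Ptpro, a receptor phosphatase, rose (1.33, SE 0.206, adjusted p = 0.0447, higher in 3 of 3 comparisons). In all 1 gene rose and 21 fell among 10643 (edgeR's quasi-likelihood test). Enterocyte genes were lower in 17 of 17 and fell as a list among the UMIs of goblet-like cells (adjusted p = 7.05e-26; adjusted p = 0.363 with an estimated correlation), with 2 members passing and 12 adjusted over the list alone. By camera 4 lists rose and 8 fell in goblet-like cells, of which 0 passed with an estimated correlation. Among those that fell were 2 that can reflect cell quality, mitochondrially encoded genes (12 of 13 lower) and dissociation stress genes (16 of 18 lower). Their camera adjusted p was 0.00576 for both, and 0.603 and 0.483 with an estimated correlation. Normal stem cell genes rose, with higher values in 15 of 16 (adjusted p = 1.68e-06; adjusted p = 0.363 with an estimated correlation), as did tuft genes, in 5 of 6 (adjusted p = 0.000385; adjusted p = 0.363 with an estimated correlation). Fetal and regenerative genes fell, with lower values in 11 of 12 (adjusted p = 1.04e-07; adjusted p = 0.363 with an estimated correlation), as did interferon-stimulated genes, in 14 of 16 (adjusted p = 1.52e-08; adjusted p = 0.483 with an estimated correlation). Without AAV-Ctrl replicate 2 the calls of Slc34a2 (−5.42) and Serpina1b (−0.74) were lost, and without AAV-Ctrl replicate 1 that of Ptpro (1.37). Leaving out 1 library at a time gave 1 to 40 higher and 52 to 190 lower genes.

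In the other classes tested no single gene passed. Adenoma-like cells gave 0 of 14140 genes (612 with an unadjusted p under 0.05, lowest adjusted p 0.197, DESeq2 14 higher and 27 lower). Cycling progenitor-like cells gave 0 of 11063 (537 with an unadjusted p under 0.05, lowest adjusted p 0.0504, DESeq2 2 higher and 33 lower), and enterocyte-like cells 0 of 11350 (490 with an unadjusted p under 0.05, lowest adjusted p 0.283, DESeq2 11 higher and 11 lower). By camera 1 list rose and 7 fell in adenoma-like cells, 2 rose and 8 fell in cycling progenitor-like cells, and 2 rose and 6 fell in enterocyte-like cells, of which 0 passed with an estimated correlation. Mitochondrially encoded genes were lower in 13 of 13 in adenoma-like (camera adjusted p = 2.87e-05) and cycling progenitor-like cells (1.5e-06). Dissociation stress genes fell in the latter too, in 13 of 18 (camera adjusted p = 0.0278). In adenoma-like cells the Wnt target (adjusted p = 0.00256; medians −1.20, 0.06 and −0.02 in D4, D1 and D2) and adenoma lists (adjusted p = 2e-04; −1.53, 0.02 and −0.08) fell, each with adjusted p = 0.605 with an estimated correlation. This class was named on members of both lists, so these results are not independent of the naming. The D4 pair filled different adenoma-like clusters, of which 1 held 175 and 17 cells, another 93 and 64, and 1 more 63 and 0. In cycling progenitor-like cells adenoma genes fell (adjusted p = 1.01e-10; adjusted p = 0.283 with an estimated correlation; 7 of 13 members adjusted over the list alone), with medians of −0.77, −0.86 and −1.22, whereas in the whole epithelium they were at 0.25 and 0.06 in D1 and D2. These cells also lay in different clusters, of which 1 held 83 and 464 cells of the D4 pair and 22, 16 and 29 of AAV-Ctrl D1-2, D1 and D2, another 0 and 0, and 66, 144 and 331, and 1 more 88 and 211, and 4, 4 and 0. Enterocyte genes fell as a list among the UMIs of adenoma-like cells, with Rbp2 at −1.37 (SE 0.123) and Apoa1 at −1.61 (SE 0.153) (adjusted p = 3e-27; adjusted p = 0.605 with an estimated correlation; 9 of 18 members adjusted over the list alone). They fell among the UMIs of cycling progenitor-like cells too, with Rbp2 at −1.26 (SE 0.148) and Apoa4 at −1.49 (SE 0.217) (adjusted p = 5e-35; adjusted p = 0.283 with an estimated correlation; 14 of 17 members adjusted over the list alone). RNA from other cells was not removed from these counts, and in barcodes with more than 200 and fewer than 500 UMIs, which hold free RNA, the enterocyte list had medians of −0.14, −0.96 and −1.03 in D4, D1 and D2. Within enterocyte-like cells 10 of 18 had higher values, and the list did not pass (adjusted p = 0.672). These cells lay in different clusters, of which 1 held 222 and 50 cells of the D4 pair, another 212, 0 and 61 of AAV-Ctrl D1-2, D1 and D2, and 1 more 0, 87 and 1. Without AAV-RSPO1-Fc replicate 3, 31 genes were higher and 84 lower in enterocyte-like cells. Without AAV-Ctrl replicate 2, 12 were higher and 23 lower in adenoma-like cells, again at a spread from D1 against D2 alone.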

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

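For the gap between the sets, the tests on normal mucosa, Rspo1 and the sex of the cells and the UMI range of that on free RNA were chosen only after the result was seen. The interaction test called 391 genes in epithelial-like cells whose treatment difference differed between the D1-2 and the D4 set, with its spread from D1 against D2 alone and 1 library per group in D4, so that 1 unusual D4 library gives the same result, and the adenoma-like share, treated minus control, was −17.47 percentage points in D4 and had the opposite sign in D1 and D2, a difference between sets that was not tested. Loss of adenoma-like cells to the cell filters was argued against by barcodes with more than 200 and fewer than 500 UMIs, where the adenoma markers had a median log2 ratio of −2.73 in D4, while the planned range of 10 to 100 UMIs was void because it held 129 and 124 CPM of Xist in the D4 pair, whose cells held 0.079 and 0.227 CPM. For a collected piece with less adenoma and more normal mucosa of like makeup, the treated over control fold of the stem-like share was 3.38 times that of the enterocyte-like share. This passed the bound, which was written after the result, but cannot decide. The enterocyte-like class mixed a cluster that fell in D4 (222 and 50 cells) with others that rose (194 and 297, 103 and 268, 125 and 204). The stem-like cells were 1 cluster that AAV-RSPO1-Fc D4 mostly filled, and the goblet-like and cycling progenitor-like shares rose there too. The sex of the cells was argued against. Among cells with Y-linked UMIs and no Xist the adenoma-like share was 9.56 percentage points above its control in D1 and −19.68 from it in D4. A wrong label or absent vector expression in AAV-RSPO1-Fc D4 cannot be told apart from an effect of treatment, since Rspo1 stood at 0.069 CPM there, near its control, and the protein can be made in another tissue, and a tissue piece of other makeup, the D label, the animals and the chemistry of the set were not tested and stay open.

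For mast cell proteases in goblet-like cells, the tests per barcode, on free RNA in barcodes with more than 100 UMIs and without cells rich in these UMIs were chosen only after the result was seen. The planned range was void for the D1-2 set, because free RNA of AAV-RSPO1-Fc D2 held 90.7 CPM of Y-linked genes while its cells held 0.033 CPM. In barcodes with more than 200 and fewer than 500 UMIs the mean log2 ratio of Mcpt1 and Mcpt2 was −0.84 in D2, and with more than 100 and at most 200 it was −0.18, both above the bound of −1.0 set beforehand against free RNA as the cause, which did not allow for the unlike numbers of barcodes in these ranges (55985 and 10830 in AAV-Ctrl D1-2 and D2 in the former) or for cells rich in these UMIs. Free RNA from mast cells therefore cannot be told apart from a change within the cells, since both ranges together, with 68209 and 67847 barcodes, gave −1.08, or −1.60 per barcode, against −2.13 per goblet-like cell without cells of at least 10 of these UMIs, while D4 gave −3.35 and −6.17 from 5 UMIs in treated cells. For the D4 set the range of more than 100 and at most 200 UMIs was void too, with 96.2 and 69.9 CPM of Xist in AAV-Ctrl D4 and AAV-RSPO1-Fc D4. Both ranges together still held RNA nearly absent from the cells, at 5.04 CPM of Y-linked genes in D2. In the D4 pair they held 51.4 and 40.7 CPM of Xist, so these ratios may be affected by RNA from elsewhere. Capture together with a mast cell as the whole cause was argued against, since the ratio without such cells was at most −2.01 in any comparison. A part of such capture cannot be told apart, with 58.1% of these UMIs of epithelial-like cells in cells of at least 10 in AAV-Ctrl D1-2 and 28.6% in AAV-Ctrl D4. The fall was not particular to goblet-like cells. In AAV-Ctrl D4 the median of both genes per cell was 2 in goblet-, adenoma-, cycling progenitor- and enterocyte-like cells, and 2.5 in 6 plasma cell-like cells. In AAV-Ctrl D1-2 it was 1 or 2, and in each treated library it was 0 in every one of these classes. These values argue against a change confined to goblet-like cells, and leave free RNA open.

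For enterocyte transcripts in goblet-like cells, the tests in barcodes with more than 100 UMIs were chosen only after the result was seen. In barcodes with more than 200 and fewer than 500 UMIs the median log2 ratio of the enterocyte list was −1.03 in D2, against −1.73 in goblet-like cells. Free RNA from enterocytes cannot be told apart from a change within goblet-like cells, since the medians lay within 0.75 of each other in that range and with both ranges together (−0.98), but not with more than 100 and at most 200 UMIs (−0.55), where the numbers of barcodes were unlike (12224 and 57017 in AAV-Ctrl D1-2 and D2). The enterocyte-like share was itself lower in D1 and D2 than in their control, and no other test of this pattern was run. List medians in D4, D1 and D2 were −0.28, −1.10 and −1.25 in adenoma-like and −0.57, −1.27 and −1.41 in cycling progenitor-like cells. They were −0.42, −1.16 and −1.73 in goblet-like and −0.43, 0.55 and 0.12 in enterocyte-like cells. These values argue against a change confined to goblet-like cells, and leave free RNA open.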

How the results depend on the processing

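Most values kept their reading under the alternative settings, but nearly all calls of gene lists were lost with another test of lists, and the counts of called genes and the adenoma-like share moved. A gene or list kept its reading if its direction and its side of the 0.05 threshold were unchanged. No epithelial gene passed in the planned test, so for those genes an unchanged direction without a call was enough. DESeq2 called 35 higher and 145 lower epithelial genes where the quasi-likelihood test called 0 and 0, and leaving out 1 library gave 0 to 70 and 0 to 719. Without the adenoma-like and unnamed clusters, an alternative added after the data were seen, 2 were lower (Mcpt1 at −4.06 and Mcpt2 at −3.41), and Bambi (0.55), Lgr5 (0.71) and Znrf3 (0.29) were higher rather than lower. Without the set covariate Lgr5 (0.08), Lgr6 (0.22) and Apc (0.052) changed sign. Apc also changed sign with DESeq2 (0.003), with library totals (0.02) and at most 10% mitochondrial UMIs (0.04), as did Rnf43 in the last (−0.079). Leaving out 1 library reversed the pooled log2 fold change of Id2 (−1.82 to 0.05), Tph1 (−3.54 to 0.57), H2-DMb1 (−0.20 to 2.56), H2-Eb1 (−0.25 to 2.91), Lgr4 (−0.75 to 0.21), Lgr5 (−0.97 to 0.12), Lgr6 (−8.54 to 0.20), Znrf3 (−2.08 to 0.15), Rnf43 (−0.14 to 0.14) and Apc (−0.037 to 0.017). The medians of adenoma genes (−3.62 to 0.13) and MHC class II genes (−0.33 to 2.91) turned too, as did camera's direction for mitochondrially encoded genes (medians −0.42 to −0.048). Without either D4 library that pair drops out of the comparison, and without AAV-Ctrl replicate 2 the D4 pair alone sets treated against control at a spread from D1 against D2, which accounts for the reversals in those fits. Of the gene lists 4 were higher and 7 lower, against 0 and 0 with an estimated correlation and 0 and 1 with fry (TGF-beta response, adjusted p = 0.00172). At most 10% mitochondrial UMIs gave 11 lower, and leaving out 1 library gave 4 to 6 and 7 to 12. With a CPM of at least 200, 5 rather than 15 genes were 2-fold lower in all 3 single comparisons, since fewer reach that level. The adenoma-like share in D4 differed by −13.9 percentage points at Leiden resolution 0.5, −14.2 with doublets kept, −15.3 with at least 1500 UMIs, −32.9 with the unnamed clusters whose best class was adenoma and −19.7 among cells with Y-linked UMIs and no Xist. The last 2 were added after the data were seen. In D1 it differed by 5.91 with at most 10% mitochondrial UMIs, 8.47 with doublets kept and 17.5 with those unnamed clusters. In D2 these were 4.11, 4.92 and 6.58, and 6.44 at resolution 0.5. Among cells with Xist and no Y-linked UMI the cycling progenitor-like share in D1 was −0.65 points from its control rather than 1.58 above. Among cells with Y-linked UMIs and no Xist it was higher, at 5.18% against 0.93%. With no filter on low counts, adenoma-like cells gave 21 higher and 57 lower genes, cycling progenitor-like cells 37 and 145, enterocyte-like cells 8 and 18, goblet-like cells 74 and 325, and the interaction 742 and 194. DESeq2 gave 14 and 27, 2 and 33, 11 and 11, and 6 and 59 in these 4 classes. Leaving out 1 library gave 0 to 12 and 0 to 23 in adenoma-like, 0 to 2 and 0 to 5 in cycling progenitor-like, 0 to 31 and 0 to 84 in enterocyte-like, and 1 to 40 and 52 to 190 in goblet-like cells. Other causes were not tested. Of the remaining comparisons of a setting with the planned analysis, 1020 planned and 137 added ones on single genes, lists and shares, and 84 and 10 on the main counts and shares, gave the same reading. Of the planned ones 43 were stronger, 30 weaker and 19 moved, and of the added ones 2 were stronger, 1 weaker and 5 moved. The values given before count 31 planned and 4 added reversals, and 56 planned and 5 added moves of the main counts and shares. The interaction cannot be fitted with a library left out, as 0 residual degrees of freedom, or no comparison within 1 of the sets, would be left. The D4 pair was taken to vary like the other libraries. The kept cells of the D4 set had fewer UMIs, so that genes of low expression were less well measured there.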

Other observations

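Cells holding Rspo1 transcripts were 106 of 3600 kept cells in AAV-RSPO1-Fc D1 (2.94%, 2.42 to 3.55) and 126 of 3036 in AAV-RSPO1-Fc D2 (4.15%, 3.47 to 4.92), against 2 of 2959 in AAV-Ctrl D1-2 (0.068%). In AAV-RSPO1-Fc D2 they were 8.35% of enterocyte-like cells (45 of 539) and 3.69% of adenoma-like cells (37 of 1004). In D1 they were 3.13% (14 of 448) and 3.95% (48 of 1215). Median UMI counts of these populations were 17958, 22880.0, 20061 (20060.5) and 21508, in that order. In AAV-RSPO1-Fc D4, 5 of 2346 cells held Rspo1, and 12 of its 15 UMIs lay in 2 of 16 fibroblast-like cells. Its control had 1 such cell of 1896.

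With a minimum of 1500 UMIs, a setting tried beside the main one, more immune cells were kept. Mast cell-like cells were 3.18% of kept cells in AAV-Ctrl D4 and 0.143% in AAV-RSPO1-Fc D4, and 1.53%, 0.257% and 0.411% in AAV-Ctrl D1-2, D1 and D2. T cell-like cells were 1.21% and 5.63% in the D4 pair, and 2.73%, 1.73% and 1.16% in the other set. Macrophage and monocyte-like cells were 1.12% and 3.17% in the D4 pair, and 1.78%, 3.18% and 1.49% in the other set. Among the UMIs of T cell-like cells, from which RNA of other cells was not removed, 0 genes rose and 3 fell among 3760 by edgeR's quasi-likelihood test (169 with an unadjusted p under 0.05). They were Mcpt1 (log2 −4.47, adjusted p = 0.00107), Wfdc18 (−2.55, adjusted p = 0.0494) and Apoa1 (−1.65, adjusted p = 0.0494). The mean log2 ratio of Mcpt1 and Mcpt2 in barcodes with more than 200 and fewer than 500 UMIs, which hold free RNA, was −2.95, −2.54 and −0.84 in D4, D1 and D2. In macrophage and monocyte-like cells 0 of 5392 passed (174 with an unadjusted p under 0.05, lowest adjusted p 0.0624). This test was added after the data were seen. An epithelial cluster led by the gastric genes Atp4a, Cldn18 and Pgc held 19, 3, 11, 68 and 21 cells in AAV-Ctrl D4, AAV-RSPO1-Fc D4, AAV-Ctrl D1-2, D1 and D2. A cluster led by Tff1, Wfdc2 and Tff2 held 70 cells of AAV-Ctrl D4 and 2 of AAV-Ctrl D1-2. Cells with both Xist and Y-linked UMIs were 15.8% of kept cells in AAV-Ctrl D1-2 and 8.03% in D1.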
